A study of Homo sapiens with 2 samples.

How the data were processed

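Gene expression was measured in A549 cells, an established human lung adenocarcinoma line, after transfection with a small interfering RNA (siRNA) against CRMP2A or with a scramble control siRNA. CRMP2A is the long isoform of collapsin response mediator protein 2, a microtubule-binding protein encoded by DPYSL2. Per the labels' protocols, cells grew for 72 hours after transfection, total RNA was extracted with Trizol, and biotin-labelled cRNA was made from 6 ug of total RNA for hybridization to 1 Affymetrix array per transfection. The array carries several probe sets for many genes.

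The deposited table holds 48306 probe sets and 1 value column per array. The authors' values were read as log2 signals from their range, 3.13 to 14.84 on the array labelled CRMP2A siRNA and 3.11 to 14.86 on the scramble array, outside the control probe sets. The submitters' processing notes name Transcriptome Analysis Console 4.0.2. The background correction, the normalization and the way probes were summarised are not given in the sources used here. The medians of the deposited log2 columns were 6.95 and 6.93. Whether they were scaled to each other before deposit is not known. Values carry 2 decimals, which makes exact ties possible. Scanner intensities and detection calls were not used here, so background on each array could not be measured and a low value cannot be told from no expression.

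Of the probe sets, 78 were manufacturer controls and were left out of all gene results. Of the other 48228, 44034 had 1 gene symbol in the probe table, 1794 had several and 2400 had none listed. Symbols were checked through gene identifiers against a RefSeq table of the GRCh38.p14 assembly, where 44007 probe sets matched and all of these kept their symbol. No genome build is named for the probe sets, so genomic positions are not given. A gene's value was that of its probe set with the highest mean over both arrays. A gene was kept if the higher of its 2 values reached 6.94, the median of all non-control values, which left 10605 of 17961 genes. Because the filter reads the higher value, a gene near the bottom of the scale on 1 array passes it when it is brighter on the other.

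With 1 array per group there is no spread between replicates. No p-value is given, and each difference is the log2 value of the array labelled CRMP2A siRNA minus that of the scramble array. Genes were counted by a fixed size of 2-fold. The only error that the table allows is the disagreement between probe sets of a gene on the same arrays. Over the 6128 genes with 2 or more probe sets past the filter, the pooled within-gene SD of the log2 difference was 0.22. That figure leaves out differences between dishes, transfections, RNA preparations and hybridizations. The number of arrays limits the precision.

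Gene lists for 32 pathways, cell states and cell types were fixed before the data were examined, as were the size rule, the filter, the alternatives and the rule for naming genes. For each list the median difference of the members past the filter was set against the medians of 10000 random lists of the same size, matched on mean level in 20 bins, and is given as a percentile. A list was said to stand apart at a percentile of at most 2.5 or at least 97.5. Percentiles were computed for the 30 lists with at least 5 members past the filter, of which chance would put 1.5 outside those limits if genes varied independently. Genes of a pathway vary together, so the percentile describes these 2 arrays and is not a test of the transfection. List members with older names were matched through 15 synonyms. List members without a probe set of a single gene name were not analysed here. The result of 1 list is not reported here, although it is among the lists counted.

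Named genes are all DPYSL2 probe sets and the other members of its family, the 15 genes with the highest and the 15 with the lowest difference whose probe sets past the filter share a sign, up to 4 members with the largest differences of each list that stood apart or had at least 2 members that differed 2-fold, and CDH1, VIM, MKI67, CDKN1A, IFIT1, ACTB and GAPDH at any value. CAV1, TNS3, TRIB3, SLC7A5, PSAT1, THBS1, COL4A1, CCN2, H4C3, MMP14, ADAM9 and MMP7 were chosen after their values were seen. EREG, XBP1, ATF4, H2BC21, H4C8, NQO1, AKR1B10, FTL and TKT were also chosen after their values were seen. So were the other genes named in the closing section.

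Alternatives were centring each array on its median, quantile normalization, loess centring of the difference over mean level with a span of 0.3, no level filter, a filter at the 75th percentile, the mean of a gene's probe sets, only probe sets without an _s_at or _x_at ending (endings that mark probe sets open to other transcripts), a linear offset of 16, thresholds of 1.5-fold and 3-fold, and random lists drawn without matching. An alternative value was called moved when it differed by more than the SD of the random-list medians, or for a gene by more than the robust spread of genes of similar level.

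The calculations were tested on simulated data for this comparison with all 10605 genes, 200 of them changed, and noise of the within-gene size. The 2-fold rule recovered 44.5% of genes changed by 1 on the log2 scale, 99.0% of those changed by 1.5 and 100.0% of those changed by 2, with 0 unchanged genes called. That noise leaves out differences between dishes, transfections, RNA preparations and hybridizations. These figures therefore check the calculation and are not error rates of the 2-fold calls. The list test instead shuffled the observed differences among the genes. Of 200 random lists of 20 genes, 5.5% stood apart with no shift and 86.5% with a shift of 0.3. Shuffling makes genes independent, so the share with no shift follows from the limits. It says nothing about pathway lists whose genes vary together. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.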

Results

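The series compared A549 lung cancer cells 72 hours after transfection with a CRMP2A siRNA and with a scramble siRNA, to set their expression profiles side by side. Each group was represented by 1 array, so no difference below has a replicate check. Another label abbreviates the first group as KO and calls the second wild-type, whereas both were transfected with an siRNA. Over the non-control probe sets the 2 arrays correlated with a Pearson r of 0.98, across probe sets that are not independent. The RNA quality controls were close, with a 3' minus 5' log2 signal of 0.68 on the array labelled CRMP2A siRNA and 0.56 on the scramble array for ACTB, and of -0.05 and -0.07 for GAPDH.

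The targeted gene was not lower. DPYSL2, which encodes CRMP2, had 4 probe sets past the level filter, and the log2 difference ranged from 0.05 to 0.14 over them. The brightest probe set read 12.35 on the array labelled CRMP2A siRNA and 12.24 on the scramble array, a log2 difference of 0.11 or 1.08-fold, at percentile 65.9 among genes of similar level. The annotation used here ties none of the 4 probe sets to the long isoform, and an array of this kind reads mostly the 3' part of transcripts that the isoforms may share. The measurement therefore checks neither the labels nor the loss of CRMP2A, and every direction below rests on the labels alone. Of the other family members, DPYSL4 was 1.61-fold higher (0.69) and DPYSL3 1.52-fold higher (0.60) in their brightest probe sets, while other probe sets gave values down to 0.15 and 0.05. All 4 CRMP1 and all 3 DPYSL5 probe sets lay below the filter. Among 15 measured kinases and binding partners of CRMP2, none differed 2-fold and the list did not stand apart (percentile 6.17).

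The array labelled CRMP2A siRNA had lower values than the scramble array for DNA replication and mitosis genes and EPCAM. It had higher values for the lists of immediate early genes, TGF-beta targets and integrins, among others. Of 10605 genes past the filter, 398 (3.75%) were at least 2-fold higher and 242 (2.28%) at least 2-fold lower. At 4-fold the counts were 41 and 11. The central 90% of genes lay between -0.72 and 0.87, with a median of 0.03. Among the 365 genes at 2-fold that had several probe sets past the filter, all probe sets shared a sign for 349 (95.6%), against 73.0% of the genes under 2-fold. This contrast follows largely from the selection on size, given a within-gene SD of 0.22. The probe sets also share the same 2 arrays, so it is no check of the 2-fold calls.

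**Figure D1:**
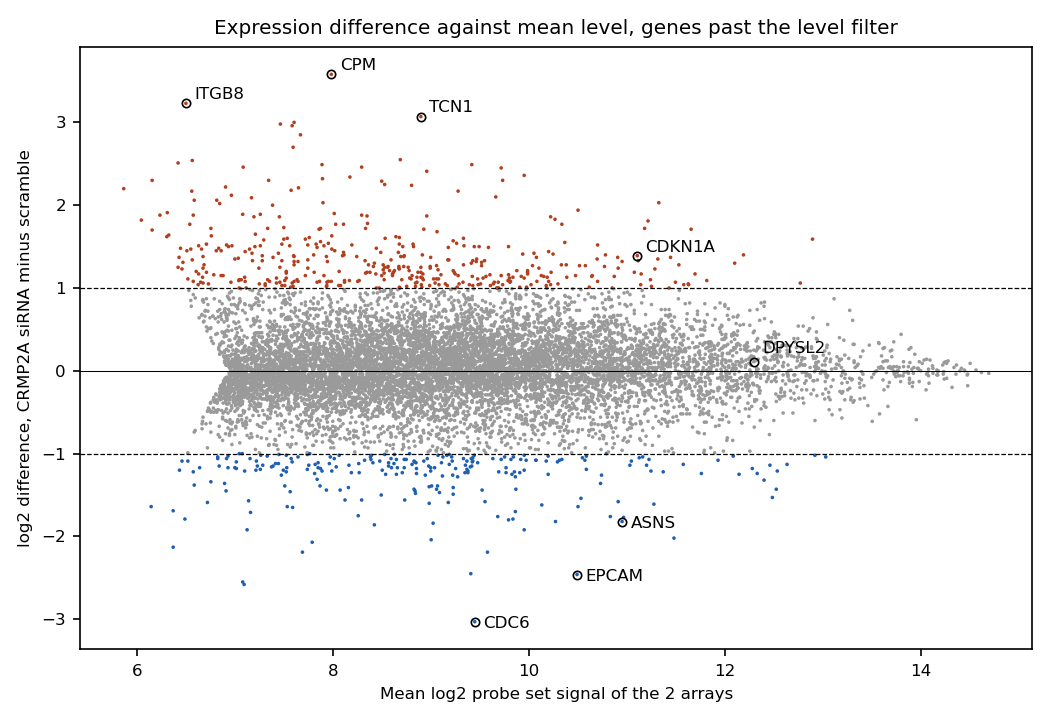
Each point is 1 of the 10605 genes past the level filter. The x axis is the mean log2 signal of the 2 arrays and the y axis the log2 difference, CRMP2A siRNA minus scramble. Dashed lines mark 2-fold, with the 398 higher genes in red and the 242 lower genes in blue. DPYSL2 lies near 0 at 0.11, whereas CPM at 3.58 and CDC6 at -3.03 lie at the extremes; the empty wedge at the left edge comes from the filter on the higher of the 2 values.

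The genes with the greatest positive differences included cell surface and secreted proteins. CPM, a membrane carboxypeptidase, had a log2 difference of 3.58 (from 2.68 to 3.58 over 3 probe sets). ITGB8, an integrin beta subunit, read 8.11 on the array labelled CRMP2A siRNA and 4.88 on the scramble array (3.23). TCN1, a vitamin B12 carrier, was 8.40-fold higher (3.07). CD14, a co-receptor for lipopolysaccharide, had differences of 2.91 and 2.96 in its 2 probe sets. The acute-phase protease inhibitor SERPINA3 (2.55), the growth factor carrier FGFBP1 (2.49) and the secreted protein PIP (2.46) followed. Also among the 15 were UNC13A, a synaptic vesicle priming factor (9.10 against 6.10), STMN3, a tubulin-binding stathmin (2.98, and 4.83 in its other probe set), the granins SCG2 (2.70) and CHGB (2.49, from 1.73 to 2.49 over 4 probe sets), and the pentraxin NPTX1 (2.46). ZMAT3, a zinc finger RNA-binding protein (2.85, and 2 in its other probe set), GBP3, an interferon-inducible GTPase (2.54), and CABCOCO1 (2.51) completed it. For 11 of these 15 genes the scramble value lay below the level filter of 6.94, where a value cannot be told from no expression, so the size of the difference is uncertain.

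The lowest gene was CDC6, the replication origin licensing factor, which was 8.17-fold lower (-3.03, and -2.12 in its other probe set). EPCAM, an epithelial adhesion molecule, was 5.50-fold lower and its 3 probe sets agreed within -2.46 and -2.42. CENPK, a kinetochore subunit (-2.45), WDR12, a ribosome assembly factor (-2.19), and RPL22L1, a ribosomal protein paralog (-2.02), were also lower. So were BPGM, which makes 2,3-bisphosphoglycerate in red cell glycolysis (-2.55), ASNS, asparagine synthetase (-1.82), and MAP2, a microtubule-associated protein (-2.13). The transporters and channels in this group were AQP3 (-2.04, but from -2.04 to -0.77 over 3 probe sets), LRRC8B (-2.19, and -1.50 in its other probe set) and SLC39A6 (-1.92). UMAD1 (-2.58), MNS1 (-1.92), DCDC2 (-1.86) and FAM3C (-1.84) completed the 15. FAM3C rested on the probe set chosen, since another of its 4 probe sets gave -0.06. For 5 of these 15 genes the value on the array labelled CRMP2A siRNA lay below the level filter.

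**Figure D2:**
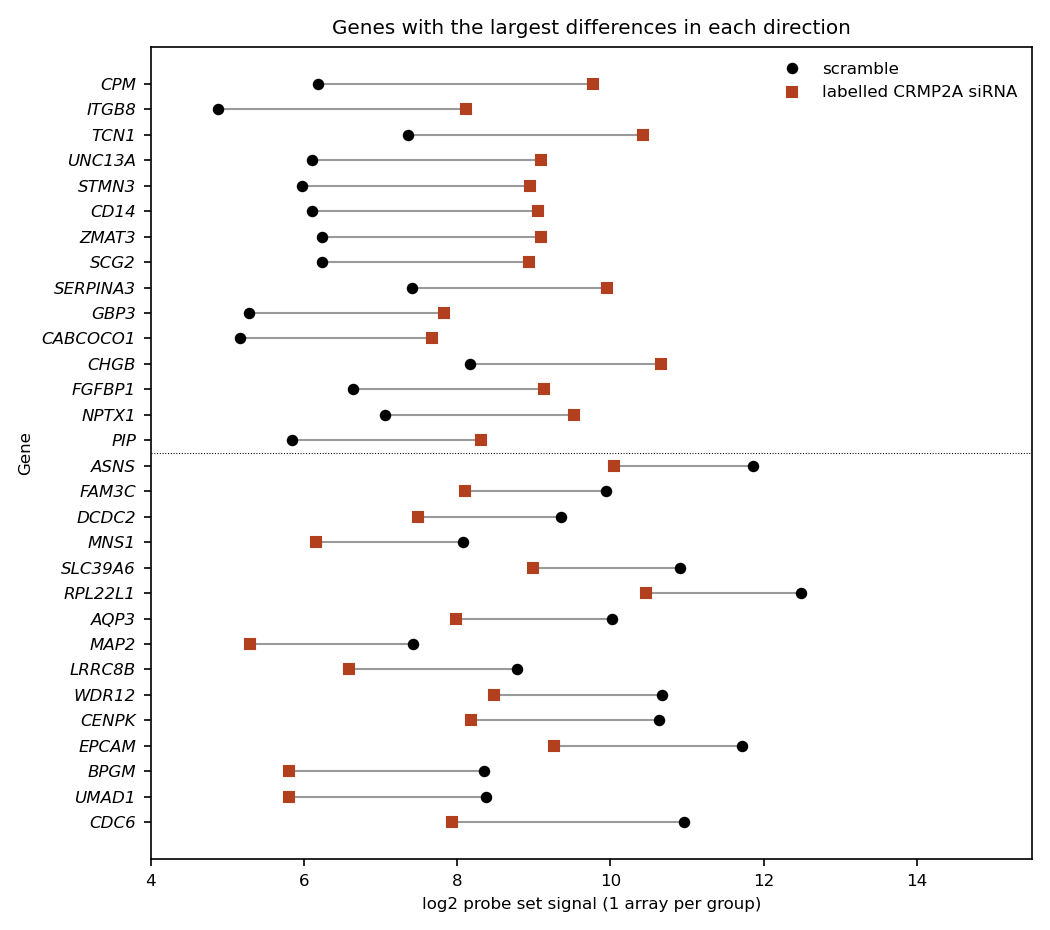
The x axis gives the log2 probe set signal and each line is 1 gene, with the scramble array as a black circle and the array labelled CRMP2A siRNA as a red square. Above the dotted line are the 15 genes with the highest differences, from CPM at 3.58 to PIP at 2.46, and below it the 15 with the lowest, from ASNS at -1.82 to CDC6 at -3.03. There is 1 array per group and no error bar.

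Cell cycle genes were lower almost without exception. Of 22 G1/S and DNA replication genes past the filter, 21 had a negative difference, 7 were at least 2-fold lower and none was 2-fold higher. Their median was -0.88 (1.84-fold lower, percentile 0 of the 10000 random lists). The lowest were CDC6 (-3.03), the helicase subunit MCM4 (-1.76, from -1.78 to -1.69 over 5 probe sets), the helicase cofactor CDC45 (-1.46, from -1.46 to -0.80 over 3 probe sets) and UHRF1, a maintenance methylation factor (-1.18). The value of CDC45 on the array labelled CRMP2A siRNA (6.83) lay below the level filter. All 24 G2/M and mitosis genes were negative, 5 of them by 2-fold, with a median of -0.72 (1.65-fold lower, percentile 0). The lowest were the spindle checkpoint genes BUB1B (-1.23) and BUB1 (-1.04), cyclin CCNA2 (-1.04) and the spindle motor KIF11 (-1.03). MKI67, the Ki-67 proliferation antigen, was at -0.23 in its brightest probe set and between -1.13 and -0.23 over 6 probe sets. Of 7 replication-dependent histone genes past the filter, 6 were positive and 3 were 2-fold higher (H1-2 at 1.31, H2BC12 at 1.30 and H2BC5 at 1.04; H2AC6 was at 0.69), with a median of 0.69 (percentile 99.8). The brightest of them, H4C3, was negative (-0.42). H2BC21 and H4C8, which are counted as positive, had scramble values below the level filter (6.58 and 6.55). Fewer than 5 histone genes were left under the stricter level filter or without _s_at and _x_at probe sets, so no percentile was computed there. Histone genes are near-identical copies, so their probe sets may read each other's transcripts.

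CDKN1A, the cyclin-dependent kinase inhibitor p21, was 2.62-fold higher in its brightest probe set, with log2 differences of 1.39 and 1.46 in its 2 probe sets. The apoptosis regulators did not stand apart (percentile 48.8), and none of 15 differed 2-fold.

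Most measured members of the integrin, matrix protease and actin lists had positive differences, with exceptions in each. The integrin and focal adhesion list had a median of 0.37 (percentile 99.98), with 15 of 19 members positive. ITGB8 (3.23), ITGA3 (1.60, and 0.98 in its other probe set) and ITGA2 (1.16) were 2-fold higher, whereas the kinase SRC was at -0.88, CAV1 at -0.81 and TNS3 at -0.63. Matrix proteases and their inhibitors had a median of 0.65 over 12 members (percentile 100), led by the protease inhibitor SERPINE2 (1.81), the urokinase PLAU (1.25), the lysosomal protease CTSL (1.06) and the urokinase receptor PLAUR (0.78). MMP14 (-0.40), ADAM9 (-0.21) and MMP7 (-0.13) were negative. Without the level filter the median of this list was 0.04, at percentile 79.1. Serum response factor targets and actin cytoskeleton genes had a median of 0.29 over 20 members (percentile 99.8), with TAGLN (1.86, from 1.27 to 2.43 over 6 probe sets), ACTA2 (1.24) and ZYX (1.02) 2-fold higher, CNN2 at 0.78 and ACTB at -0.34. TGF-beta targets had a median of 0.43 over 19 members (percentile 100), of which PMEPA1 (1.77) and LTBP2 (1.06) were 2-fold higher, with JUNB at 0.94 and BHLHE40 at 0.87. JUNB is also in the immediate early list. Of the TGF-beta targets 5 were negative, among them THBS1 (-0.69), COL4A1 (-0.50) and CCN2 (-0.48). The scramble values of TAGLN (6.52) and LTBP2 (6.14) lay below the level filter, so the size of their differences is uncertain. The YAP and TAZ targets did not stand apart (median 0.09, percentile 72.1), with CRIM1 at 1.28 and AJUBA (-1.10), CCN1 (-0.78) and GADD45B (-0.64) on the other side.

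Epithelial and mesenchymal genes differed in opposite directions, and each list held exceptions. Of 16 epithelial genes, 11 were negative and the median was -0.16 (percentile 1.71). EPCAM (-2.46) and the tight junction gene OCLN (-1.23) were 2-fold lower, CLDN1 was at -0.72 and CDH1, E-cadherin, at -0.61, while the keratin KRT19 was 2.64-fold higher (1.40). Of 14 mesenchymal genes, 10 were positive with a median of 0.27 (percentile 99.0). The collagens COL5A1 (1.47, from 0.70 to 1.99) and COL6A1 (1.19, but 0.07 in its other probe set) and the repressor ZEB1 (1.26, from 0.91 to 1.26 over 6 probe sets) were 2-fold higher, SNAI1 was at 0.97 and VIM at 0.33 in both of its probe sets. The scramble values of COL5A1 (6.41) and SNAI1 (6.76) lay below the level filter. The epithelial list lost its place outside the limits with quantile normalization (percentile 4.63), no level filter (14.95), the stricter filter (18.9), without _s_at and _x_at probe sets (5.27) and without matching (3.33). The mesenchymal list lost its place with the stricter filter (96.1), without _s_at and _x_at probe sets (92.6) and without matching (97.49). The fibroblast markers, a list for another cell type, had 5 of 15 members past the filter. LUM (2.20), FBN1 (1.73) and COL3A1 (0.98) were higher, each from a scramble value below the filter (4.76, 6.63 and 6.27). With probe sets below the filter included, differences ran from 0.02 to 1.73 for FBN1 and from 0.06 to 1.36 for COL3A1. FBLN1 (-0.17, but up to 0.54 over 6 probe sets) and COL1A1 (-0.11) were not higher. The median of the fibroblast markers, 0.98, turned to -0.03 when no level filter was used. Of the blood and endothelial markers 3 passed the filter, and CD14 was the one that differed 2-fold.

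Tubulins stood apart with a median of -0.24 over 11 members (percentile 0.95), but none differed 2-fold. Of these members 6 were negative and 5 positive, with a mean of -0.05, so the list was not lower as a whole. TUBE1 (-0.85) and TUBB (-0.35) were lower, whereas TUBB3 (0.61) and TUBB6 (0.46) were higher. With the filter at the 75th percentile the tubulin median was -0.03 (percentile 24.5), and without _s_at and _x_at probe sets too few tubulins were left for a percentile. The microtubule regulators did not stand apart (percentile 49.1) because members went both ways, with TPPP (1.72), the plus-end protein MAPRE1 (1.71) and MAP1B (1.52) 2-fold higher and 2 members 2-fold lower, of which MAP2 (-2.13) was the lower. The scramble value of TPPP (6.47) lay below the level filter. Semaphorins, plexins and neuropilins, the extracellular guidance system in which CRMP2 was described, had a median of 0.09 (percentile 74.5). NRP2 (1.27, but down to 0.24 over its 5 probe sets), SEMA4B (1.17) and L1CAM (1.05) were 2-fold higher and PLXNB2 was at 0.91, but at 0.01 in another of its 4 probe sets. This list stood apart above the random lists with the filter at the 75th percentile (median 0.88, percentile 99.98) and without _s_at and _x_at probe sets (0.33, percentile 99.3). With the mean of a gene's probe sets its median was -0.035 (percentile 30.0). The scramble value of L1CAM (6.72) lay below the level filter.

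**Figure D3:**
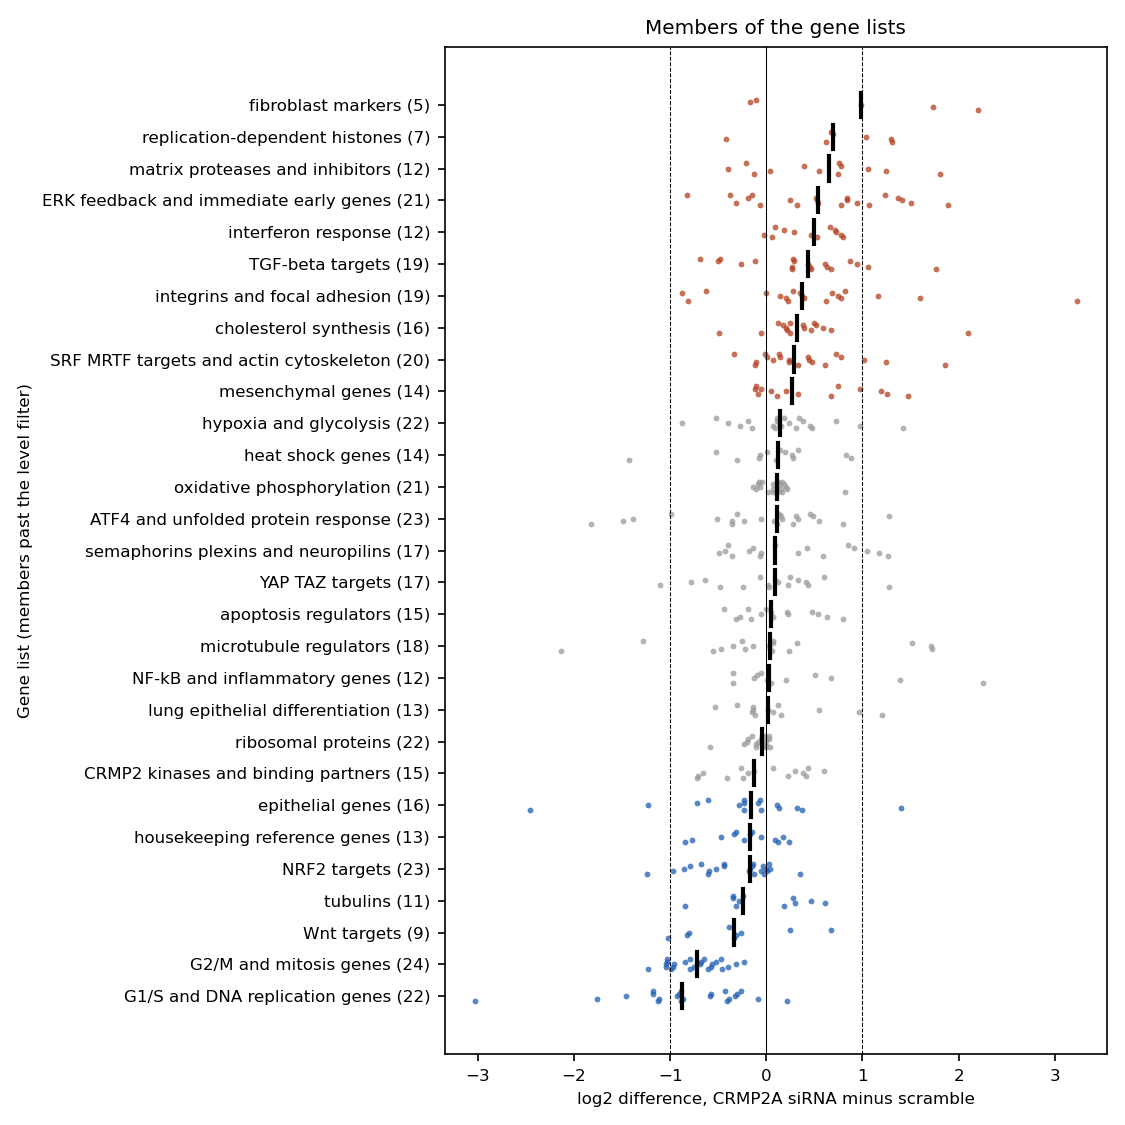
Each row is a gene list with a percentile, other than 1 list not reported here, each dot a member past the level filter, and the x axis its log2 difference, CRMP2A siRNA minus scramble. Black bars are list medians, dashed lines mark 2-fold, and red and blue dots belong to lists that stood apart above and below the random lists. The 2 cell cycle lists at the bottom have medians of -0.88 and -0.72, with 45 of 46 members below 0.

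Signalling and stress genes were mixed. The list of ERK feedback and immediate early genes had a median of 0.54 over 21 members (percentile 100), with 6 members 2-fold higher and none lower by that much. JUN (1.89), the ERK inhibitor SPRY2 (2.83-fold), IER2 (1.41) and FOS (1.37) had the greatest differences. Of the 21 members 6 were negative, among them MYC (-0.82), which is also in the Wnt list, and EREG (-0.38). The scramble value of JUN (6.13) lay below the level filter, so the size of its difference is uncertain. The same holds for IFIT2 (6.53) and CXCL8 (6.90), named next. Wnt targets had a median of -0.34 over 9 members (percentile 0.75), among them DKK1 (-1.02), MYC (-0.82) and BMP4 (-0.80), with TCF7L2 at 0.67 (up to 1.12 over 4 probe sets). NRF2 targets, which are constitutively high in this KEAP1-mutant line, had a median of -0.17 over 23 members (percentile 0.24). ALDH3A1 was 2-fold lower (-1.24), and SRXN1 (-0.97), OSGIN1 (-0.86) and GCLC (-0.79) were close behind. Of the members 18 were negative and 4 positive. Some bright members were nearly level, such as NQO1 (0.04), AKR1B10 (-0.03) and FTL (-0.02), and TKT was at 0.35. The interferon response list stood apart (median 0.50 over 12 members, percentile 99.6) with ISG15 at 0.80, IFI35 at 0.78, IFI6 at 0.73 and IFIT2 at 0.71, although none reached 2-fold and IFIT1 was at 0.09. The median was 0.20 with no level filter, still apart (percentile 99.98), and too few of these genes passed the stricter filter for a percentile. Of the NF-kB and inflammatory genes, C3 (2.25) and CXCL8 (1.39) were 2-fold higher, CXCL5 was at 0.67 and TNFAIP2 at 0.51, and the list did not stand apart (percentile 53.8). The ATF4 and unfolded protein response list did not stand apart (percentile 83.9), with 13 of 23 members positive, a median of 0.11 and a mean of -0.10. ASNS (-1.82), PHGDH (-1.49) and CHAC1 (-1.39) were 2-fold lower, and XBP1 (-0.99) and ATF4 (-0.51) were also negative. VLDLR was 2-fold higher (1.28), while TRIB3 (0.80), SLC7A5 (0.33) and PSAT1 (0.13) were positive. The value of CHAC1 on the array labelled CRMP2A siRNA (6.81) lay below the level filter.

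Cholesterol synthesis genes had a median of 0.32 over 16 members (percentile 99.2), of which 14 were positive, but the percentile was 95.3 with the stricter filter. SC5D, a late enzyme of the pathway, was 4.29-fold higher (2.10, from 1.70 to 2.16 over 4 probe sets), with MSMO1 at 0.67, IDI1 at 0.59 and FDPS at 0.52. Lists that did not stand apart were ribosomal proteins (median -0.04, but -0.43 at percentile 0.05 without _s_at and _x_at probe sets), oxidative phosphorylation (0.11), hypoxia and glycolysis (0.14), heat shock genes (0.12) and lung epithelial differentiation (0.02, and -0.03 with quantile normalization). Common reference genes were not level between the arrays. Their list had a median of -0.17 over 13 members (percentile 1.96), with GUSB at -0.84, TFRC at -0.77, IPO8 at -0.47, ACTB between -0.53 and -0.34 over 3 probe sets, and GAPDH at 0.09. The percentile was 3.10 with probe set means, 4.61 without _s_at and _x_at probe sets and 4.40 without matching.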

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

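Both values here come from probe sets that the comparisons above leave out, and neither was chosen before the data were seen. Of the bacterial RNA spikes read by the manufacturer's control probe sets, thr had a median log2 difference of 0.925 over 6 probe sets (from 0.54 to 1.39), against 0.26 for dap, 0.29 for phe and 0.13 for lys. The hybridization controls bioB, bioC, bioD and cre had median differences of 0.20, 0.15, 0.13 and 0.04. Of 1981 probe sets past the filter that carry no gene name or several, 71 were at least 2-fold higher and 47 at least 2-fold lower in the array labelled CRMP2A siRNA. These shares were close to those of the named genes (3.75% and 2.28%), so these probe sets did not stand out.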

How the results depend on the processing

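All alternatives here were chosen before the data were examined. No paired analysis was possible because each group has 1 array. No replicate could be left out for the same reason. The DPYSL2 difference stayed between 0.08 and 0.14 under every alternative. The counts of 398 higher and 242 lower genes became 239 and 161 with the filter at the 75th percentile, 255 and 155 with the mean of a gene's probe sets (233 and 141 of them shared with the original calls), 1129 and 795 at 1.5-fold, and 87 and 36 at 3-fold. Quantile normalization gave 349 and 277, and loess centring 353 and 278. No scaling moved the median of all genes by more than 0.05. Of the 18 lists that stood apart, all 18 did so after median centring, loess centring and the linear offset, 17 after quantile normalization, 16 with probe set means, 15 with no filter, 15 without matching, 12 over probe sets without _s_at or _x_at endings, and 11 with the stricter filter. Some of these losses are of lists left with under 5 members. Lists that stood apart only under an alternative were the CRMP family with no filter (0.35, percentile 98.5), semaphorins and plexins with the stricter filter (percentile 99.98) and without _s_at or _x_at probe sets (99.3), and ribosomal proteins without those probe sets (0.05). The CRMP family median of 0.35 is the value of DPYSL5, whose probe sets, like those of CRMP1, all lay below the level filter. Both cell cycle lists stood apart throughout. The fibroblast median of 0.98 reversed to -0.03 with no filter. It was -0.17 with the stricter filter, which is the value of FBLN1. Without _s_at and _x_at probe sets it was -0.04, again with under 5 members left. With no filter the medians were 0.17 for mesenchymal genes, 0.04 for matrix proteases and 0.20 for interferon response. With the stricter filter they were 0.88 for semaphorins and plexins, -0.03 for tubulins, 0.43 for actin cytoskeleton genes, -0.05 for epithelial genes and -0.60 for Wnt targets. Other lists had under 5 members left there, so their values say little about the list. These were 0.11 for the CRMP family (the value of DPYSL2), 2.96 for blood markers (the value of CD14), 0.35 for lung differentiation and 1.17 for histones. With probe set means they were 0.29 for the CRMP family, 0.05 for CRMP2 partners, -0.035 for semaphorins and plexins, 0.38 for actin cytoskeleton genes and -0.28 for NRF2 targets. Without _s_at and _x_at probe sets they were 0.33 for semaphorins and plexins, -0.41 for tubulins, 0.38 for actin cytoskeleton genes, 0.50 for integrins, -0.78 for replication genes, 0.47 for cholesterol synthesis, 0.34 for ERK and immediate early genes, -0.43 for ribosomal proteins and 1.04 for histones. Tubulins and histones had under 5 members left in that last setting. The cause of these shifts was not tested. Random lists without matching put epithelial genes at percentile 3.33, mesenchymal genes at 97.49 and reference genes at 4.4. Of 913 values of single named genes under the alternatives, 29 moved by more than the spread of genes of similar level and none reversed. FAM3C became -0.08 with median centring, -0.14 with quantile normalization and -0.06 without _s_at and _x_at probe sets, where another of its probe sets was taken. With 1 array per group, no setting tells a difference between transfections from a difference between dishes.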

Other observations

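Further genes are named here after their values were seen. The cholesterol exporters ABCA1 and ABCG1 were 5.31-fold (log2 difference 2.41) and 4.72-fold higher (2.24) in the array labelled CRMP2A siRNA, whereas the apolipoproteins APOC1 (-0.73) and APOE (-0.12) were not. BDNF, a neurotrophin, was 2.83-fold higher, and the synaptic scaffold MAPK8IP2 (2.34, from 1.04 to 2.34 over 3 probe sets) and the secreted olfactomedin OLFM1 (2.18) were higher. The scramble value of OLFM1 (6.48) lay below the level filter. SNAP25, the synaptic membrane fusion protein, was at -0.84 and CPLX2, a complexin, at -0.80.

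Of the tests below, those on culture density, fibroblast RNA, DPYSL2 and the REST transcript were chosen after the result was seen, and the REST and LXR target lists were written after the top genes were known. The cell cycle medians as deposited were known before their tests were written, and the values of the REST and LXR lists without the level filter were added after the filtered ones were seen. The first pattern is the lower cell cycle expression, with a median of -0.77 over the 46 members of both lists together. Were a level-dependent trend between the arrays its source, loess centring would bring it towards 0, but the median was then -0.82. Probe sets shared with other genes do not account for it either, since the median was -0.78 over probe sets without _s_at or _x_at endings. A denser or older culture in 1 of the 2 dishes stays open: YAP and TAZ targets, which fall at high density, had a list median of 0.09 with members on both sides. An effect of the siRNA, through CRMP2A or another transcript, cannot be told apart from it with 1 dish per group.

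The second pattern is the higher expression of matrix genes that fibroblasts also make (LUM, FBN1, COL3A1 and COL5A1). Fibroblast RNA in the array labelled CRMP2A siRNA would bring COL1A1, COL1A2 and DCN, which fibroblasts express strongly. The highest difference among 5 COL1A1 probe sets was 0.02, and the median differences were -0.08 for COL1A2 and -0.13 for DCN, which argues against that source. All COL1A2 and DCN probe sets and all COL1A1 probe sets but 1 (at -0.11) lay below the level filter, where a loss would not be seen, but a gain would be, as for LUM from 4.76 to 6.96. A change within the A549 cells may remain, as a hypothesis that these arrays do not test further.

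The third pattern is that DPYSL2 was not lower. Probe sets that read all DPYSL2 transcripts may hide a loss of a minor long isoform. The differences of the 4 probe sets lay within 0.09 of each other. Without any loss they would also lie close together, so this does not tell which transcripts each probe set reads. Exchanged labels were not excluded, since the highest DPYSL2 difference of 0.14 is too small to point either way. Both stay open because no probe set used here is annotated to the long isoform. Whether the siRNA lowered CRMP2A at all was not decided for the same reason.

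Several genes of the top 15, such as SCG2, CHGB, STMN3 and UNC13A, are known targets of the repressor REST, and a wider release of REST target genes was a candidate explanation. The 15 listed targets past the filter that had not been seen before had a median of 0.05, at percentile 60.9 of random lists, with BDNF and INA (1.05) among them higher and SNAP25 (-0.84), CPLX2 (-0.80) and SNAP91 (-0.42) lower. Without the filter the percentile of 36 such targets was 83.4. The prediction that a low percentile would count against a release was wrong by design, because the tested list leaves out the targets already seen to be higher. Over all 24 listed targets past the filter the median was 0.25 at percentile 99.3 (99.8 without the filter), with 10 members 2-fold higher and 0 2-fold lower, but that list holds the genes that prompted it. The hypothesis stays open. The brightest REST probe set was at -0.04 but lay below the level filter, so a lower REST transcript was not decided. A wider rise of LXR target genes was tested because ABCA1 and ABCG1 are LXR targets. Leaving out these and ABCA3, which had also been seen, the 8 targets past the filter had a median of 0.48 at percentile 99.7, with SMPDL3A at 1.25, SREBF1 at 0.73 and APOC1 at -0.73. The scramble value of SMPDL3A (6.83) lay below the level filter. Over 13 targets without the filter the percentile was 53.8. By the filtered value alone the hypothesis would have been met; the requirement that both values agree was set after they were seen, and it stays open.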
